A study of Homo sapiens with 9 samples.

How the data were processed

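RNA was measured on 9 Affymetrix 3′ expression arrays, 3 each from HDFA cells (primary human dermal fibroblasts) given sham, nanosecond electric pulse (nsEP) or heat shock exposure. Per the labels' protocols, cells were grown at 37 °C in 5% CO2 and 95% humidity. They were brought to 1200 cells per µl, exposed in an electroporation cuvette and harvested at 4 h. Total RNA was column purified, and biotin-labelled cRNA was made from 1 µg of it by a modified in vitro transcription procedure. The temperature and duration of the heat shock are not given in the sources used here.

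The deposited values are log2 signals of 54675 probe sets per array, with 0 missing values. Per the submitters' processing notes, the signals were made with MAS5, which combines the perfect match and mismatch probes of a probe set into 1 signal. The software version, scaling target and detection calls are not given in the sources used here. On the linear scale, the mean signal after leaving out the lowest and highest 2% of probe sets was 500.1 on every array, so each array had been scaled to 1 common level. A change of most transcripts in 1 direction would be hidden by such scaling, and every change given here is relative to it. The deposited log2 values went into the tests with no further normalization. MAS5 subtracts a background and has no floor, so log2 signals of dim probe sets vary widely and their fold changes are imprecise. For arrays the number per group, 3, limits the precision.

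The 62 control probe sets were left out of the tests and used only as measures of array quality. Of the other 54613 probe sets, the 27306 whose mean log2 signal over the 9 arrays was above 6.56, the median of those means, were tested. Gene symbols came from the platform annotation supplied with the data. Of the 54613 probe sets 41091 carried 1 gene symbol, 1801 several and 11721 none. Among those tested the numbers were 22852, 1058 and 3396. The Entrez identifiers of 41037 of the single-gene probe sets were found in the RefSeq table of assembly GRCh38.p14, and 0 symbols changed through it. No gene is named from a probe set with several symbols, for which reason HSPA1A and HSPA8 are not reported here. No genome build was given for the array, and no coordinates are printed. The tested single-gene probe sets covered 12555 genes, each represented in gene lists and among the named genes by its brightest tested probe set. Other probe sets of a gene could differ: 3 genes had probe sets called in both directions between nsEP and sham, 113 between heat shock and sham, and 63 between nsEP and heat shock.

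All comparisons were made in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. A linear model with 1 mean per group was fitted to all 9 arrays, and the moderated test of limma was applied with an intensity trend in the variance prior. P-values are two-sided and were adjusted by the method of Benjamini and Hochberg over the probe sets tested. A probe set was called at an adjusted p under 0.05, and "rose" or "fell" is written only of called genes. Log2 differences are given with the standard error (SE) of the model, group means with the standard deviation (SD). Measures of array quality were compared by exact permutation tests, whose smallest possible two-sided p for 3 against 3 arrays is 0.1.

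A total of 30 gene lists for stress responses, signalling, matrix, cell cycle, organelles and cell types were fixed, with the design and the rule for naming genes, before the data were examined. The 26 lists with at least 5 tested members were tested with camera, which asks whether a list's genes moved more than other genes. The preset correlation between genes was 0.01, and p-values were adjusted over the lists of a comparison. Camera was repeated with a correlation estimated from these arrays, under which 0 list calls held in any of the 3 comparisons. With fry, which asks whether a list's genes moved on balance in 1 direction, 2 lists were called between nsEP and sham, 9 between heat shock and sham and 7 between nsEP and heat shock. The 2 were the immediate early and cholesterol synthesis lists. Members were also counted with p-values adjusted over the list alone.

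The genes named are, for each comparison, the 10 largest rises and 10 largest falls among called single-gene probe sets whose groups did not overlap. Added to them are up to 4 called members of each list with the largest change, or the 2 brightest members where none was called, and a fixed set of stress genes (HSPA6, DNAJB1, HSPH1, BAG3, FOS, EGR1, JUN, ATF3, DUSP1, DDIT3, CDKN1A, HMOX1, IL6, CXCL8, PTGS2, CCN1, CCN2, ANKRD1 and MT2A among them). The text gives a selection of these. Genes outside this rule are said to have been chosen after their values were seen.

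The labels number the arrays of each group 1 to 3. Deviations of same-numbered arrays from their group means correlated across probe sets between nsEP and sham, with r = 0.348, 0.241 and 0.233 for numbers 1, 2 and 3. As all exceeded 0.1, the numbers were taken to pair the arrays of that comparison, and a fit with the replicate number as a block was set beside the unblocked one where it changed a call. The labels do not say what the shared number stands for.

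The sham arrays serve both exposures, which makes the 2 comparisons with sham share chance values. Their correlation was set against 100 simulated draws of unchanged groups sharing the sham arrays. The procedure was tested on simulated data with 200 changed probe sets among the 27306 tested. At a simulated change of 2-fold, 46.3% were recovered between nsEP and sham, 49.3% between heat shock and sham, and 52.2% between nsEP and heat shock. At 4-fold the shares were 93.9%, 92.4% and 90.9%, and at 1.5-fold 7.5%, 9.0% and 14.9%. False calls made up 5.8%, 7.4% and 3.7% of calls. The simulations gave 104, 108 and 109 calls, fewer than the data did. With more calls the adjusted threshold is less strict, so these recovery shares need not hold for the data. A gene list shifted by 0.5 on the log2 scale was called, and 0 of 25 other lists were. Simulated noise was drawn independently for each probe set, so list calls under correlation between genes were not tested.

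Alternatives fixed in advance were signals raised by 16 or 64 before the log, quantile normalization, median centring, 3 other filters, the replicate block, a fit to only the arrays compared, other variance priors, array weights, each gene's mean over its probe sets, other list tests, and leaving out each array in turn. Centring on spike-in or ribosomal protein probe sets, and leaving out heat shock arrays 2 and 3, were chosen after seeing the data.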

Results

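HDFA cells are primary fibroblasts of human dermis. Gene expression was measured 4 h after sham exposure, exposure to 100 electric pulses of 10 ns at 150 kV/cm (nsEP), or heat shock, with 3 arrays per group. The labels call the arrays of a group biological replicates without saying whether they came from separate cultures or donors. P-values therefore measure the spread between these arrays, which may in part be technical.

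Heat shock arrays stood apart from the others. Across the tested probe sets, arrays of 1 group correlated with r from 0.966 to 0.971 (sham), 0.963 to 0.969 (nsEP) and 0.953 to 0.962 (heat shock), and arrays of different groups with r from 0.902 to 0.967. The first principal component held 43.5% of the variance and separated heat shock from both other groups, and the second held 16.1%. Measures of RNA quality were compared with too few arrays to exclude a difference. The log2 ratio of 3′ to 5′ signal of ACTB was 0.71 ± 0.22 (SD, n = 3) after sham, 0.63 ± 0.19 after nsEP and 1.02 ± 0.24 after heat shock (exact permutation p = 0.3 for heat shock against sham). It was highest on heat shock arrays 2 and 3, at 1.18 and 1.14. The same ratio of GAPDH was 0.06 ± 0.14, -0.07 ± 0.14 and 0.21 ± 0.15 (exact permutation p = 0.3 for heat shock against sham). Spike-in transcripts added before hybridisation were equal after sham and nsEP (12.41 ± 0.16 and 12.40 ± 0.09) and higher by 0.45 after heat shock (12.86 ± 0.23; exact permutation p = 0.1, the smallest possible).

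All 10 measured fibroblast markers were bright, with a median log2 signal of 12.6 after sham, 12.7 after nsEP and 12.1 after heat shock. As scaled, the lower median after heat shock does not mean a general fall. Gene by gene, 8 of the 10 were higher than after sham, with a median difference of 0.12. Their largest difference, 0.405, was below the spike-in rise of 0.449, so with spike-in centring all 10 would be lower. Markers of other skin cells were mostly below the signal required for testing: 3 of 10 keratinocyte, 3 of 8 melanocyte, 3 of 9 endothelial and 2 of 9 leukocyte markers exceeded it. None of these markers was called by limma between nsEP and sham, where 1 melanocyte and 1 endothelial marker had an unadjusted p under 0.05. The melanocyte regulator MITF differed by 0.65 ± 0.18 (SE) in that comparison, with an adjusted p of 0.0755, and of 0.0463 with the replicate block. After heat shock KRT10, a keratin of differentiating epidermis, rose by 0.74 ± 0.13 and MITF by 1.31 ± 0.18. The keratinocyte marker DSP (-0.655) and the leukocyte marker CD3E (-1.24) were lower, called only when adjusted over the list alone. The melanocyte marker TYR differed by -0.60 and was not called. The fibroblast transcription factor PRRX1 fell by 1.30 ± 0.19.

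The first comparison asked which transcripts differed 4 h after the pulses. Of 30 immediate early genes, transcription factors and feedback regulators that cells switch on within minutes of a stimulus, 9 rose after nsEP and 21 were not called (camera adjusted p = 3.1e-11; adjusted p = 0.383 with an estimated correlation). FOS was 27.9-fold higher (log2 difference 4.80 ± 0.60, SE, n = 3 arrays per group), the orphan nuclear receptor NR4A2 14.5-fold (3.86 ± 0.51) and the stress-induced factor ATF3 9.12-fold (3.19 ± 0.25). Of 12 genes of cholesterol synthesis under the factor SREBP2 5 rose (camera adjusted p = 4.9e-09; adjusted p = 0.383 with an estimated correlation), led by the sterol sensor INSIG1 at 4.33-fold (2.11 ± 0.23) and the enzyme gene HMGCS1 at 3.76-fold (1.91 ± 0.26). NEU1, which encodes a lysosomal sialidase, was 6.24-fold higher (2.64 ± 0.18, adjusted p = 4.9e-05). The glycogen phosphorylase gene PYGB showed the largest named fall, 8.14-fold (-3.02 ± 0.33). Heat shock chaperones were not called by their brightest probe sets.

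None of the 30 immediate early genes fell, and 16 rose adjusted over the list alone, with a mean log2 difference of 0.95 for the list. Besides FOS, NR4A2 and ATF3, KLF2 rose 5.59-fold (2.48 ± 0.29). EGR1 (0.36 ± 0.23, adjusted p = 0.441), JUN (-0.09 ± 0.13) and DUSP1 (0.64 ± 0.21, adjusted p = 0.118) were not called, and DUSP1 had an adjusted p of 0.0301 with the replicate block. Another DUSP1 probe set was called (1.94 ± 0.42, adjusted p = 0.0284; chosen after its values were seen), though not without sham replicate 1 or 3 or nsEP replicate 2 or 3 (adjusted p up to 0.126). With the block 12 of the 30 genes rose and 0 fell. The sham signal of FOS (5.31) lay below the level required for testing, so its fold is imprecise.

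None of the 12 genes of cholesterol synthesis fell, and 8 rose adjusted over the list alone. Their mean difference was 0.87, and 11 of 12 were higher. MSMO1 rose 3.09-fold (1.63 ± 0.25) and IDI1 2.68-fold (1.42 ± 0.14). INSIG1, HMGCS1, MSMO1 and IDI1 kept their calls without each of the 9 arrays in turn.

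Of 22 heat shock chaperones and co-chaperones, each by its brightest probe set, limma called 0, with 2 higher and 1 lower adjusted over the list alone, and 3 higher and 0 lower with the replicate block. At an unadjusted p under 0.05, 3 were higher and 4 lower. HSPA6, the strictly inducible HSP70 gene, differed by 1.04 ± 0.43 (adjusted p = 0.222). The HSP40 gene DNAJB1 differed by 0.45 ± 0.12, with an adjusted p of 0.0620, and of 0.0222 with the replicate block. Other probe sets, chosen after their values were seen, were called for DNAJB1 (0.76 ± 0.18, adjusted p = 0.0367) and CACYBP (-0.54, adjusted p = 0.0471). That of DNAJB1 was not called without sham replicate 1 or 3 or nsEP replicate 2 or 3 (adjusted p up to 0.155). The co-chaperone genes BAG3 (0.07 ± 0.13) and HSPH1 (-0.25 ± 0.14) were not called. The list's mean difference was 0.04 and its median -0.08 (camera adjusted p = 0.933).

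Another 4 lists passed the camera test upward, with few called members. None of the 4 was called by fry (adjusted p from 0.136 to 0.468). In the ATF4 amino acid response 2 of 16 genes rose (5 adjusted over the list alone), namely CEBPB (1.05 ± 0.17) and the amino acid transporter subunit SLC3A2 (0.79 ± 0.18). The camera adjusted p was 0.00415, and the adjusted p = 0.429 with an estimated correlation. Among 13 TGF-beta responsive genes 4 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.00169; adjusted p = 0.383 with an estimated correlation). The risers included BAMBI (0.86 ± 0.16), SKIL (0.93 ± 0.23) and SMAD6 (0.81 ± 0.17), known as inhibitors of the pathway, and the matrix protein gene TGFBI fell by 0.81 ± 0.15. One of 22 NF-kB and inflammatory genes rose (3 higher and 1 lower adjusted over the list alone), the cyclooxygenase gene PTGS2 at 4.15-fold (2.05 ± 0.44). IL6 (1.35 ± 0.49, adjusted p = 0.162) and CXCL8 (-0.15 ± 0.24) were not called, and the list's adjusted p was 0.00169 by camera (adjusted p = 0.660 with an estimated correlation). Of 8 histone genes H2BC21 rose (0.97 ± 0.20), and all 8 were higher (camera adjusted p = 0.00589; adjusted p = 0.429 with an estimated correlation).

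The calls of CEBPB, KLF2, NR4A2, FOS and ATF3 held without each array in turn. Those of SLC3A2, BAMBI, SKIL, SMAD6, PTGS2 and H2BC21 did not: each was lost without sham replicate 1 or 3 and without nsEP replicate 2 or 3, with adjusted p up to 0.144, 0.0852, 0.186, 0.0980, 0.115 and 0.0925. TGFBI was not called without nsEP replicate 2 or sham replicate 3 (adjusted p up to 0.0825). The NF-kB and histone lists lost their calls without sham replicate 1, and the NF-kB list also without nsEP replicate 3.

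Genes of cell death and growth control changed singly. In the p53 list 0 of 21 genes rose and 2 fell (1 and 2 adjusted over the list alone), with 3 higher and 4 lower at an unadjusted p under 0.05. The p53 inhibitor gene MDM2 fell 2.04-fold (-1.03 ± 0.16) and the translesion polymerase gene POLH by 0.84 ± 0.18, while CDKN1A differed by 0.06 ± 0.25. Of 15 genes of the apoptosis machinery MCL1, which opposes cell death, rose by 0.62 ± 0.14, and CASP8 fell by 0.97 ± 0.18. A dimmer probe set of another member, BCL2L11, chosen after its values were seen, rose by 1.34 (adjusted p = 0.0340). Of 18 YAP targets 2 rose and 2 fell (mean 0.005, median -0.06), among them the Hippo kinase gene LATS2 with a rise of 1.00 ± 0.14. CCN1 (-0.55 ± 0.43), CCN2 (0.30 ± 0.59) and ANKRD1 (0.11 ± 0.36) were not called. The growth factor gene FGF7 rose by 1.32 ± 0.27 and HGF fell by 0.84 ± 0.21, as the 2 called among 17 growth factors and ligands. LATS2 and MDM2 kept their calls without each array, whereas POLH, MCL1, CASP8, FGF7 and HGF lost theirs without sham replicate 1 or 3 or nsEP replicate 2 (adjusted p up to 0.119, 0.119, 0.0708, 0.0993 and 0.195).

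Single members were called in other lists. The unfolded protein response factor ATF4 rose by 0.99 ± 0.19 and SDF2L1 fell by 1.29 ± 0.31, the 2 called of 17 genes in that list, and DDIT3 differed by -0.11 ± 0.32. CREM, a factor induced by cyclic AMP and calcium, rose by 1.63 ± 0.32 as 1 of 17 calcium responsive genes (3 adjusted over the list alone). The glutathione synthesis gene GCLM rose by 0.57 ± 0.12 as 1 of 15 NRF2 targets, where HMOX1 differed by 0.22 ± 0.18 and a dimmer probe set of AKR1C1, chosen after its values were seen, rose by 1.86 ± 0.26. ADM rose by 0.98 ± 0.23 as 1 of 16 hypoxia and glycolysis genes (3 adjusted over the list alone). ADAMTS5 rose by 1.32 ± 0.32 and TIMP3 fell by 0.77 ± 0.16 among 15 matrix proteases and inhibitors. The AKR1C1 probe set was called without each array in turn. Each of the other calls named here was lost without sham replicate 3, nsEP replicate 2 or both of them, and all but that of SDF2L1 without sham replicate 1, with adjusted p up to 0.174. None of these lists passed the camera test (adjusted p = 0.968, 0.0891, 0.310, 0.0724 and 0.926).

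In 10 of the 26 lists tested with camera limma called 0 members by their brightest probe sets, adjusted over all probe sets or over the list alone; with the replicate block 1 respiratory chain gene and 1 fibroblast marker were lower. At an unadjusted p under 0.05, 0 were higher and 1 lower among 16 SRF and MRTF cytoskeletal genes, 19 membrane repair genes and 20 DNA replication genes alike. The numbers were 0 and 3 of 19 extracellular matrix genes, 1 and 1 of 10 interferon response genes and of 10 fibroblast markers, and 0 and 0 of 18 mitotic, 9 metal responsive and 14 ribosomal protein genes. The interferon and ribosomal protein lists averaged -0.13 and -0.008, while camera ranked both upward relative to other genes (adjusted p = 0.968 and 0.926). Other probe sets, chosen after their values were seen, were called for the collagen gene COL1A1 (-1.31 and -1.17) and the fibroblast markers PDGFRA (0.70) and PRRX1 (-1.70 ± 0.24, called without each array in turn). The membrane repair gene ANXA2 differed by -0.00 ± 0.11, the matrix gene FN1 by -0.00 ± 0.11 and the metallothionein gene MT2A by -0.12 ± 0.09. Among 16 genes of the mitochondrial respiratory chain, 0 and 3 passed the unadjusted p, and 15 of them were lower, by 0.17 on average. The camera adjusted p of that list was 0.0770, and 0.0433 with the replicate block (adjusted p = 0.396 with the block and an estimated correlation).

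Among single genes outside the lists, KLHL24 rose 6.32-fold (2.66 ± 0.25), the actin nucleation and p53 cofactor gene JMY 5.04-fold (2.33 ± 0.27), the Wnt receptor gene FZD10 5.00-fold (2.32 ± 0.31) and the nuclear receptor coactivator gene PNRC1 4.96-fold (2.31 ± 0.30). Falls included the long noncoding RNA SPRY4-IT1 at 7.36-fold (-2.88 ± 0.42), the vitamin B12 gene MMACHC at 3.01-fold (-1.59 ± 0.23) and the zinc finger gene ZNF18 at 3.59-fold (-1.84 ± 0.34). PYGB and SPRY4-IT1 had signals below the level required for testing after nsEP (6.02 and 5.46), which leaves the size of their falls uncertain. ZNF18 was not called without sham replicate 1 or 3 or nsEP replicate 2 (adjusted p up to 0.0743), and the others were called without each array.

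In all, 960 of 27306 probe sets were called between nsEP and sham, 506 higher and 454 lower, of which 292 and 119 changed at least 2-fold. With the replicate block 1739 were called, 874 higher and 865 lower, including 959 of the 960. The block raised the counts of list members that rose and fell to 7 and 0 for cholesterol synthesis, 6 and 1 for TGF-beta, 3 and 0 for ATF4 and for calcium, 2 and 0 for NF-kB and for hypoxia, 2 and 1 for the unfolded protein response, and 1 and 2 for p53 and for apoptosis. The count was 265 without sham replicate 1, 244 without sham replicate 3, 204 without nsEP replicate 2, 407 without nsEP replicate 3, 559 with no filter, 429 without the intensity trend and 1502 with array weights. With median centring the balance of the directions moved to 390 higher and 1130 lower of 1520. The split was 215 and 121 of 336 with spike-in centring, and 260 and 135 of 395 with ribosomal protein centring. Those centrings shifted the median of all probe sets by only 0.006 and 0.007, so their splits do not show an effect of scaling. Fits with few calls leaned higher too, with 198 of 265 without sham replicate 1 and 190 of 244 without sham replicate 3.

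**Figure D1:**
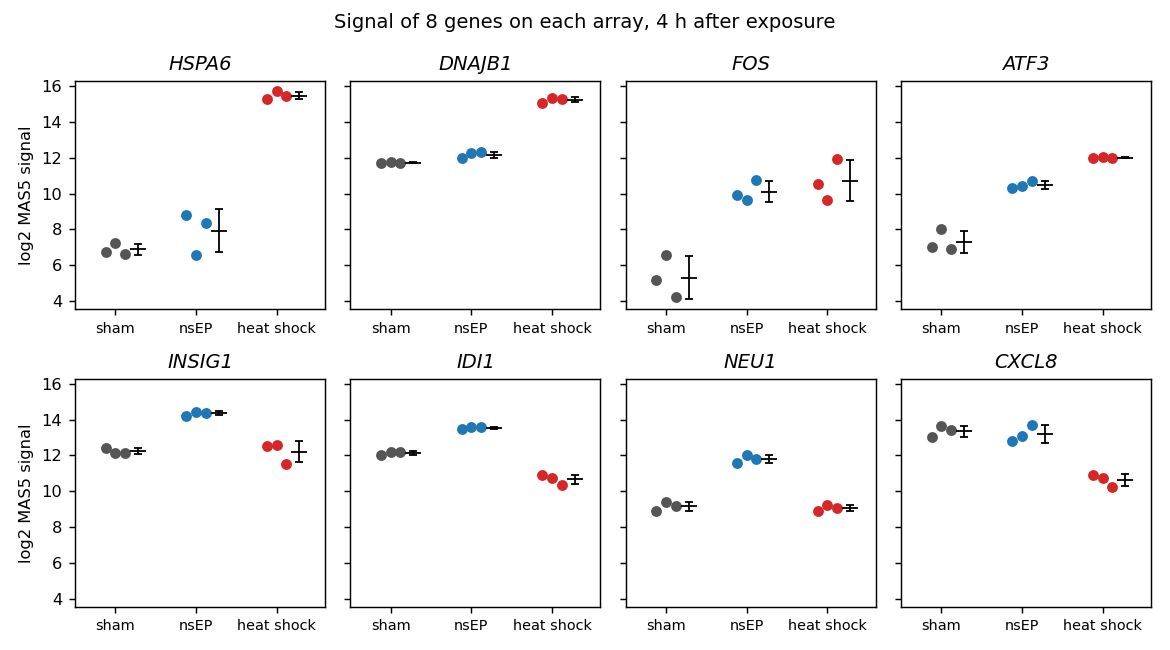
Log2 MAS5 signal (vertical axis) of 8 genes on each of the 9 arrays, grouped as sham, nsEP and heat shock, with the group mean and SD (n = 3) beside the points. HSPA6 and DNAJB1 stood 8.59 and 3.50 above sham after heat shock, against 1.04 and 0.45 after nsEP, which were not called, ATF3 and FOS were above sham after both exposures, INSIG1 and NEU1 were above sham after nsEP, IDI1 rose by 1.42 after nsEP and fell by 1.47 after heat shock, and CXCL8 fell by 2.71 after heat shock.

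Heat shock was compared with sham as an exposure with a well known transcript response. Of 22 chaperone genes 18 rose (camera adjusted p = 1.8e-13; adjusted p = 0.657 with an estimated correlation). HSPA6 was 386-fold higher than after sham (log2 difference 8.59 ± 0.43, SE, n = 3 arrays per group), DNAJB1 11.3-fold (3.50 ± 0.12), the HSP110 family gene HSPA4L 17.9-fold (4.16 ± 0.19) and the small heat shock protein gene CRYAB 9.71-fold (3.28 ± 0.32). Of 30 immediate early genes 17 rose and 4 fell (camera adjusted p = 2.5e-05; adjusted p = 0.722 with an estimated correlation), with FOS 42.5-fold (5.41 ± 0.60), ATF3 26.3-fold (4.72 ± 0.25) and NR4A1 17.6-fold (4.14 ± 0.26) higher. The Notch target genes HEY1 and HES1 rose 46.8-fold (5.55 ± 0.36) and 32.9-fold (5.04 ± 0.51). After nsEP, too, they were called higher than after sham, by 1.92 ± 0.36 and 2.06 ± 0.51 (adjusted p = 0.0172 and 0.0484), calls lost without sham replicate 1 or 3 or nsEP replicate 2 (adjusted p up to 0.0716 and 0.157). The HES1 call was also lost without sham replicate 2, nsEP replicate 3 or heat shock replicate 1. The chemokine genes CXCL5 and CXCL8 fell 10.6-fold (-3.41 ± 0.44) and 6.54-fold (-2.71 ± 0.24).

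None of the 22 chaperones fell, and 19 rose adjusted over the list alone. Their mean difference was 1.69, and 21 of 22 were higher. BAG3 rose 3.58-fold (1.84 ± 0.13) and HSPH1 2.74-fold (1.45 ± 0.14). The co-chaperone gene DNAJA4, outside the list, rose 23.4-fold (4.55 ± 0.21).

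Adjusted over the list alone 18 immediate early genes rose and 5 fell, and the list averaged 1.34. The sham signal of FOS lay below the level required for testing, as did that of EDN1, so their folds are imprecise. EGR1 rose 3.69-fold (1.88 ± 0.23), JUN fell 1.60-fold (-0.68 ± 0.13) and DUSP1 differed by -0.01 ± 0.21. The 14 ribosomal protein genes were all higher as scaled, by 0.29 to 0.39, though not with spike-in centring, and 6 of them rose (13 adjusted over the list alone; camera adjusted p = 0.000935; adjusted p = 0.846 with an estimated correlation). The examples RPL19 (0.39 ± 0.12) and RPS3 (0.34 ± 0.10) turned to -0.06 and -0.11 with spike-in centring, and the list call ended with quantile normalization, with centring on spike-in or ribosomal protein probe sets, and without heat shock arrays 2 and 3. RPL19 and RPS3 were not called without sham replicate 1 or 2 or heat shock replicate 2 or 3 (adjusted p up to 0.0980 and 0.0851). Dimmer probe sets of 2 members, chosen after their values were seen, differed in direction, with RPS24 at -1.17 and RPL37 at 0.87 and 0.54. Spike-ins on the same arrays were higher by 0.45.

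Of 15 NRF2 targets 0 rose and 7 fell (0 and 9 adjusted over the list alone; mean -0.39; camera adjusted p = 0.0107; adjusted p = 0.722 with an estimated correlation). At an unadjusted p under 0.05, 1 was higher and 9 were lower. GCLM fell 2.06-fold (-1.04 ± 0.12), the aldo-keto reductase genes AKR1C1 and AKR1C2 by 0.94 ± 0.13 and 0.87 ± 0.13, and the haem oxygenase gene HMOX1 by 0.82 ± 0.18. In cholesterol synthesis limma called 0 of 12 genes higher and 4 lower, over all probe sets and adjusted over the list alone, with 0 and 5 at an unadjusted p under 0.05. SQLE fell 3.24-fold (-1.70 ± 0.19) and IDI1 2.78-fold (-1.47 ± 0.14), while INSIG1 (-0.03 ± 0.23) and HMGCS1 (-0.05 ± 0.26) were not called, and the camera adjusted p was 0.0914. A dimmer probe set of LSS, chosen after its values were seen, rose by 0.77.

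Several lists did not pass the camera test, and many of them held changes in both directions. Their counts adjusted over the list alone are the same unless given. The YAP, TGF-beta, ATF4, calcium, apoptosis and interferon lists were called by fry (adjusted p from 0.0066 to 0.0272), though not by camera. Among 18 YAP targets 6 rose and 4 fell, with AMOTL2 12.1-fold (3.60 ± 0.27) and the LIM protein gene AJUBA 5.08-fold (2.34 ± 0.18) higher (adjusted p = 0.432). CCN2 rose by 2.11 ± 0.59, a call lost without heat shock replicate 3 (adjusted p = 0.0624). Of 13 TGF-beta responsive genes 6 rose and 1 fell (7 and 2 adjusted over the list alone; adjusted p = 0.0507). The inhibitor SMAD7 rose 7.71-fold (2.95 ± 0.19) and KLF10 4.22-fold (2.08 ± 0.17), and PMEPA1 fell 8.61-fold (-3.11 ± 0.23). In the ATF4 list 6 of 16 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.0507), led by the pseudokinase gene TRIB3 (1.72 ± 0.23). Under other settings camera called the ATF4 list in 15 of 27 and the TGF-beta list in 9 of 27. Their means of 0.475 and 0.677 were not below those after nsEP (0.471 and 0.450), so neither list sets the exposures apart. Of 22 NF-kB and inflammatory genes 3 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.876). CXCL1 fell by 1.89 ± 0.32 with CXCL8, while CCL2 (2.00 ± 0.51) and IL6 (1.93 ± 0.49) rose, calls lost without heat shock replicate 3 and sham replicate 1 (adjusted p = 0.0586 and 0.0523).

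Calcium responsive genes split into 2 higher and 5 lower of 17 (3 and 5 adjusted over the list alone; adjusted p = 0.410), with the factor genes NFATC2 and NFATC1 down 24.4-fold (-4.61 ± 0.32) and 4.12-fold (-2.04 ± 0.18) and the kinase gene SIK1 up by 2.33 ± 0.35. Of 15 matrix proteases and inhibitors 0 rose and 5 fell (adjusted p = 0.263), including the stromelysin gene MMP3 (-3.09 ± 0.49), ADAMTS1 (-2.19 ± 0.15) and TIMP3 (-1.47 ± 0.16). At an unadjusted p under 0.05, 2 were higher and 6 lower. Among 17 growth factors and ligands 3 rose and 5 fell, with HBEGF (2.62 ± 0.39) and EDN1 (2.54 ± 0.34) up and HGF (-2.43 ± 0.21) down (adjusted p = 0.558). Of 19 extracellular matrix genes 4 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.263), among them COL5A2 (1.04 ± 0.21) and POSTN (-2.20 ± 0.44). Dimmer probe sets of other members, chosen after their values were seen, were called mostly lower. They were those of COL3A1 (-3.92), COL1A2 (-1.62), COL1A1 (-0.82 and -0.72) and THBS1 (-0.58), against FBLN1 (0.63). Of 17 unfolded protein response genes 5 rose and 3 fell, with HERPUD1 higher (1.63 ± 0.32) and DDIT3 lower (-1.12 ± 0.32), a call lost without sham replicate 3 or heat shock replicate 2 or 3 (adjusted p up to 0.0805). The list's adjusted p was 0.721.

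Among 21 p53 targets 5 rose and 4 fell (adjusted p = 0.721), with PLK2 up (1.83 ± 0.34) and POLH (-1.35 ± 0.18) and MDM2 (-1.24 ± 0.16) down, while CDKN1A differed by 0.41 ± 0.25. In the apoptosis list 3 of 15 rose and 2 fell (3 and 3 adjusted over the list alone; adjusted p = 0.576), with APAF1 up by 1.35 ± 0.19. A dimmer probe set of BCL2L11, chosen after its values were seen, rose by 1.40 (adjusted p = 0.00519). The glycolytic enzyme gene HK2 fell 4.79-fold (-2.26 ± 0.25) and ADM rose 3.11-fold (1.63 ± 0.23) in the hypoxia list, where 3 of 16 rose and 1 fell (adjusted p = 0.410). Of 16 respiratory chain genes 2 rose and 3 fell, of 16 cytoskeletal genes 2 and 1, of 20 DNA replication genes 0 and 3, of 19 membrane repair genes 0 and 1, of 8 histone genes 2 and 0, of 10 interferon genes 1 and 0, and of 10 fibroblast markers 1 and 1. Adjusted over the list alone the respiratory chain counts were 3 and 3, those for DNA replication 0 and 2, and those for fibroblast markers 0 and 1. These lists had camera adjusted p from 0.142 to 0.876, and the mean and median differed in sign for the cytoskeletal genes (-0.05 and 0.02) and the respiratory chain (-0.009 and 0.006). Of 18 mitotic and 9 metal responsive genes limma called 0, with 0 and 1 at an unadjusted p under 0.05, and the metallothionein gene MT2A differed by 0.06 ± 0.09, while dimmer probe sets of MT1X (-0.58) and SLC30A1 (-0.99), chosen after their values were seen, were called (camera adjusted p = 0.721 and 0.876).

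Outside the lists, the signal of a probe set annotated to RPPH1, the RNA component of ribonuclease P, rose to 13.67 from a sham signal of 3.94, far below the level of 6.56 required for testing (adjusted p = 6.4e-08), a large rise of uncertain size. Which transcript it detects was not checked against probe sequences. The RNA-binding protein gene RBM24 rose 60.3-fold (5.91 ± 0.21) and the chemokine gene CCL26 42.8-fold (5.42 ± 0.61), from sham signals also below that level, so the folds are imprecise. The phosphatase inhibitor gene PPP1R14C fell 60.0-fold (-5.91 ± 0.78) to a signal below that level, as did POSTN, and the size of these falls is likewise uncertain. The hyaluronan synthase gene HAS2 fell 10.5-fold (-3.39 ± 0.43) and NREP 10.6-fold (-3.41 ± 0.20).

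Between heat shock and sham 6682 of 27306 probe sets were called, 3035 higher and 3647 lower, with 1201 and 1580 of them changed at least 2-fold. The split was 2183 to 4142 with median centring, 822 to 8040 with spike-in centring and 1007 to 6461 with ribosomal protein centring, so the balance of the directions is not settled. Without heat shock arrays 2 and 3, whose ACTB ratios were highest, 3096 were called, 1008 higher and 2088 lower.

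**Figure D2:**
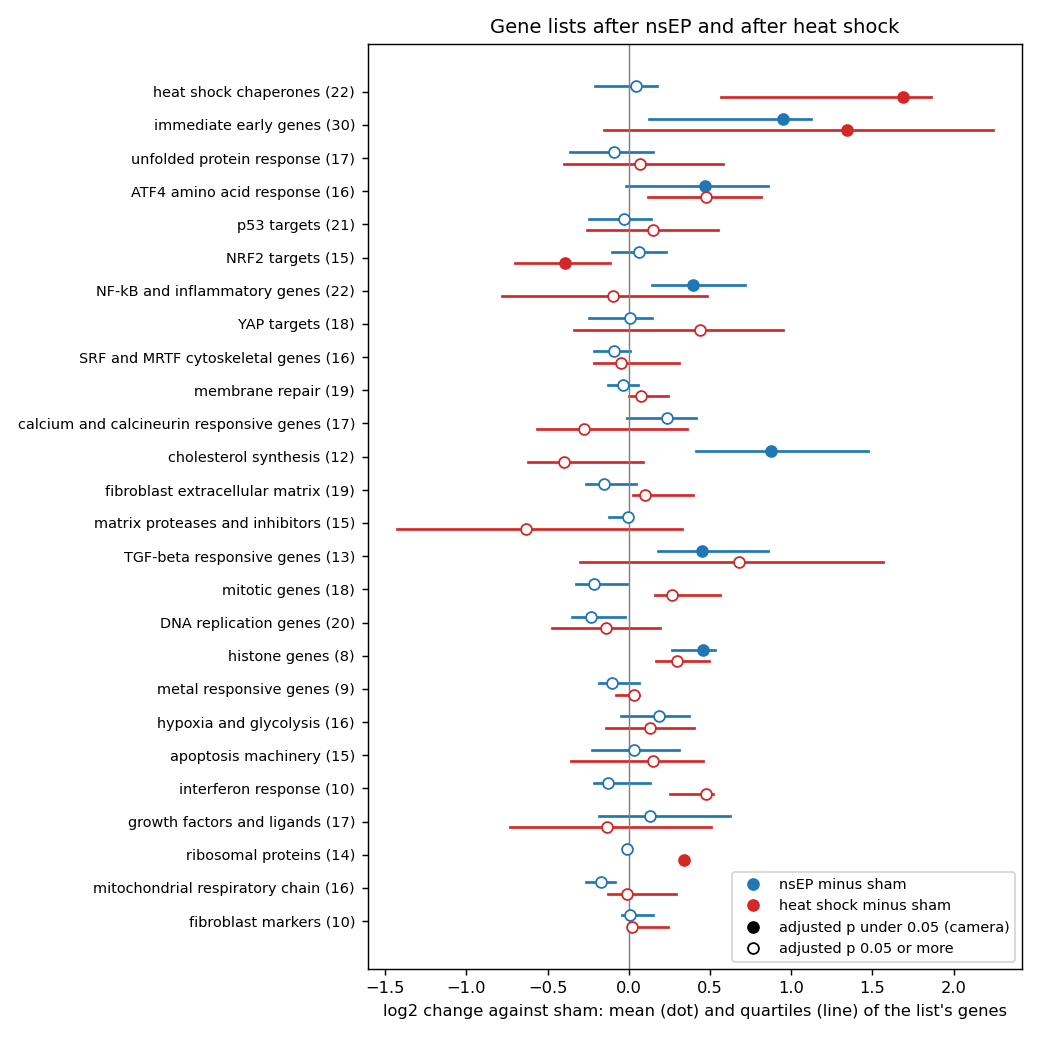
Log2 change against sham (horizontal axis) of the tested members of 26 gene lists, with the number of members in brackets; dots are means and lines run from the lower to the upper quartile over genes, for nsEP in blue and heat shock in red, filled where the camera adjusted p was under 0.05. Chaperones averaged 1.69 after heat shock and 0.04 after nsEP, cholesterol synthesis genes -0.40 and 0.87, and immediate early genes 1.34 and 0.95.

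The exposures were then compared directly. Of 22 chaperone genes 17 were lower after nsEP than after heat shock (camera adjusted p = 2.8e-13; adjusted p = 0.439 with an estimated correlation), by 187-fold for HSPA6 (-7.55 ± 0.43, SE, n = 3 arrays per group) and 8.31-fold for DNAJB1 (-3.05 ± 0.12). Of 12 cholesterol synthesis genes 9 were higher after nsEP (camera adjusted p = 2.0e-07; adjusted p = 0.439 with an estimated correlation), by 7.43-fold for IDI1 (2.89 ± 0.14), 4.54-fold for SQLE (2.18 ± 0.19) and 4.42-fold for INSIG1 (2.14 ± 0.23). The inflammatory genes CXCL8 (2.56 ± 0.24) and PTGS2 (2.19 ± 0.44) were also higher after nsEP. HES4, of the same family of Notch targets as HES1, was 24.5-fold higher after nsEP (4.62 ± 0.45), from a heat shock signal below the level required for testing, and HEY1, which had risen after both exposures, was 12.4-fold lower after nsEP (-3.63 ± 0.36).

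None of the 22 chaperones was called higher after nsEP, and 18 were lower adjusted over the list alone (mean -1.65). BAG3 (-1.77 ± 0.13), HSPH1 (-1.70 ± 0.14) and CRYAB (-3.10 ± 0.32) were among the lower ones. In cholesterol synthesis 0 were lower, over all probe sets and adjusted over the list alone, and the list averaged 1.27. Of 15 NRF2 targets 6 were higher and 0 lower (9 and 2 adjusted over the list alone; mean 0.45; camera adjusted p = 0.00114; adjusted p = 0.439 with an estimated correlation). They included GCLM (1.61 ± 0.12), AKR1C2 (1.30 ± 0.13), AKR1C1 (1.10 ± 0.13) and HMOX1 (1.03 ± 0.18).

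Of 22 NF-kB and inflammatory genes 6 were higher after nsEP and 1 lower (7 and 1 adjusted over the list alone; mean 0.50; camera adjusted p = 0.0437; adjusted p = 0.862 with an estimated correlation). CXCL2 (1.96 ± 0.46) and CXCL1 (1.81 ± 0.32) were higher. That list call also ended without heat shock replicate 2 or 3 or nsEP replicate 3, and under other scalings. All 14 ribosomal protein genes were lower after nsEP as scaled, by 0.28 to 0.43, though not with spike-in centring, and 6 of them passed the test (13 adjusted over the list alone; camera adjusted p = 0.000884; adjusted p = 0.862 with an estimated correlation). RPL19 (-0.43 ± 0.12) turned to 0.02 with spike-in centring and was not called without nsEP replicate 2 or heat shock replicate 3 (adjusted p up to 0.0847). Spike-ins were lower by 0.46 after nsEP than after heat shock, in the same direction.

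Immediate early genes differed in part. Of 30, 5 were higher and 13 lower after nsEP (8 and 13 adjusted over the list alone; camera adjusted p = 0.255). ATF3 (-1.53 ± 0.25), EGR1 (-1.52 ± 0.23), NR4A1 (-2.17 ± 0.26), JUNB (-1.90 ± 0.28) and GADD45B (-1.95 ± 0.23) were lower, JUN (0.58 ± 0.13) was higher, and FOS did not differ detectably (-0.61 ± 0.60, adjusted p = 0.508). Genes that were high after nsEP relative to heat shock included NFATC2 (4.63 ± 0.32), HAS2 (3.20 ± 0.43), MMP3 (2.97 ± 0.49), HK2 (2.62 ± 0.25) and the transporter gene SLCO4A1 (3.64 ± 0.34, from a heat shock signal below the level required for testing). AMOTL2 (-3.26 ± 0.27), SMAD7 (-2.38 ± 0.19) and AJUBA (-2.45 ± 0.18) were lower. No other list passed the camera test; the closest were the calcium responsive genes (6 higher and 3 lower of 17, with 7 and 3 adjusted over the list alone, adjusted p = 0.0568) and the extracellular matrix (1 and 8 of 19, with 1 and 10 adjusted over the list alone, adjusted p = 0.0975). The mean and median differed in sign for the ATF4 list (-0.004 and 0.05) and for hypoxia and glycolysis (0.06 and -0.04), and DNA replication genes averaged -0.09 where camera ranked them upward.

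In total 6002 probe sets were called between nsEP and heat shock, 3171 higher and 2831 lower, 1377 and 874 of them at least 2-fold. Scaling moved the split to 7646 higher and 561 lower with spike-in centring, and to 5996 and 683 with ribosomal protein centring. With median centring the split turned to 2671 higher and 3404 lower, so the balance of the directions is not settled. The count was 3811 without nsEP replicate 2, and 2526 without heat shock arrays 2 and 3, of which 1716 were higher and 810 lower.

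The calls of the exposures against sham overlapped. Of the 506 probe sets higher after nsEP, 288 were also higher after heat shock, and of the 454 lower ones 277 were also lower. Independent lists of these sizes would share 56.2 and 60.6. In the direct comparison 111 of the 288 and 60 of the 277 still differed between exposures. Of the 366 nsEP calls not called after heat shock, 254 differed between the exposures. A further 22 probe sets were higher after nsEP and lower after heat shock, and 7 the reverse, against 67.6 and 50.5 for independent lists. All 29 differed in the direct comparison, which follows from the opposite signs and is no added evidence. IDI1, GCLM and SLCO4A1 were among the 22.

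Across the 27306 probe sets, which are not independent replicates, the changes after nsEP and after heat shock correlated with r = 0.425. Simulated unchanged groups sharing the sham arrays gave a mean r of 0.462, from -0.60 to 0.99 over 100 draws. The observed covariance was 0.129 and the simulated one averaged 0.0461 (from -0.04 to 0.32), a difference of 0.0831. As the observed value lay within the simulated range, this difference cannot be told from 0. The draws also left out the correlation between same-numbered nsEP and sham arrays, so the simulated value belongs to a simpler design. The 3 sham arrays are too few to give each exposure its own controls, so part of the overlap may come from the shared controls.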

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

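The comparisons of ribosomal protein, ribosomal RNA and RPPH1 signals with the spike-ins were chosen after the results were seen; the tests of ribosomal proteins against random lists and of other RNAs without a poly(A) tail were set before their values were computed.

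Control probe sets outside the comparisons of the report stood above their sham level. Ribosomal RNA signals were higher after heat shock, by 2.43 (28S, 5′ end), 0.605 (28S, middle), 1.56 (28S, 3′ end), 0.504 (18S, 5′ end), 0.98 (18S, middle) and 1.34 (18S, 3′ end) on the log2 scale. After nsEP 2 of the 18S probe sets stood above all sham arrays, by 0.269 (5′ end) and 0.849 (3′ end). The spike-in probe sets were higher by 0.449 after heat shock.

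The first pattern weighed is the rise of ribosomal protein signals after heat shock. It was 0.108 smaller than the spike-in rise (ribosomal protein minus spike-in -0.108, SD 0.187 between arrays), a value consistent with a difference of scaling between arrays. Against random lists of equally bright genes the ribosomal protein median of 0.334 lay at percentile 92.3. It was between the 2.5th percentile of their medians, 0.108, and the matching upper percentile, 0.348. A rise beyond other abundant transcripts therefore cannot be told apart from the general shift of bright probe sets. Heat shock is the exposure that differs, and a change of ribosomal protein transcripts in the cells remains an open explanation.

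The second pattern is the rise of ribosomal RNA and of a probe set annotated to RPPH1 after heat shock, RNAs that mostly lack a poly(A) tail, though that probe set's target was not checked and the priming test bears on it only if it detects RPPH1. If more such RNA had been primed, others of the kind should have risen too. The median change of 10 others was -0.04 (SD 0.968), and RNA45SN5 rose by 2.07, H4C11 fell by 1.83 and SNORA21 fell by 0.72. This argues against priming for a rise the size of that of RPPH1 but, with this spread, leaves it open for ribosomal RNA. RNA45SN5 is the precursor of 18S and 28S, so it is no separate check on ribosomal RNA. H4C11 and H4C8 were dim after heat shock (5.70 and 6.56), so their changes are imprecise. RPPH1 exceeded the spike-in rise by 9.28 (SD 0.222), a size left uncertain by its dim sham signal. Its heat shock signal of 13.67 still lay above the testing level of 6.56 by far more than the spike-ins rose, which argues against scaling between arrays. For ribosomal RNA the smallest excess over the spike-ins was 0.055 (SD 0.241; 18S, 5′ end) and the largest 1.98 (28S, 5′ end), so scaling cannot be told apart from a change at the smallest, and no biological explanation was tested.

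In 4 gene lists the mean differences from sham had opposite signs in the 2 exposures and the direct comparison passed the camera test, though in each list only 1 of the differences from sham did. Mean log2 differences between nsEP and heat shock were 1.275 for cholesterol synthesis (0.87 and -0.40 against sham), 0.452 for NRF2 targets (0.06 and -0.39), 0.495 for NF-kB and inflammatory genes (0.40 and -0.10) and -0.349 for ribosomal proteins (-0.008 and 0.34). With an estimated correlation the adjusted p of the direct comparison was 0.439, 0.439, 0.862 and 0.862.

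Another 29 probe sets were called in opposite directions by the 2 exposures, and therefore also differed in the direct comparison. Among the 22 higher after nsEP, chosen after their values were seen, was the cholesterol export gene NPC1 (1.12 after nsEP and -0.94 after heat shock). A dimmer probe set of the cholesterol esterification gene SOAT1 (0.82 and -0.68) was another. Among the 7 lower was a dimmer probe set of the HSP90 associated gene CACYBP (-0.54 and 2.16), whose brightest probe set was not called after nsEP.

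The 6 arrays of a comparison make 10 splits into 3 and 3, too few for a share under 0.05. In each comparison 1 of the 10, the real one, gave as many calls. The real split gave 960, 6682 and 6002 probe sets for nsEP against sham, heat shock against sham and nsEP against heat shock, and the highest other split gave 1, 0 and 0. For nsEP against sham, where replicate numbers pair the arrays, the highest of the 3 other splits that part all pairs gave 1 and the rest 0.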

How the results depend on the processing

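Centring on spike-in or ribosomal protein probe sets and leaving out heat shock arrays 2 and 3 were chosen after seeing the data. Of the named calls, 19 of 49 between nsEP and sham, 66 of 105 between heat shock and sham and 55 of 109 between nsEP and heat shock held in every setting run, left-out arrays included. No called list changed its camera direction, which is relative to other genes, but the ribosomal protein mean after heat shock turned from 0.341 to -0.108 with spike-in centring. The count between nsEP and sham (960) was 1520 with median centring, 559 with no filter, 1739 with the replicate block, 429 without the intensity trend, 1502 with array weights, 336 with spike-in and 395 with ribosomal protein centring, and 204 to 1055 leaving out 1 array. Without heat shock arrays 2 and 3, which leaves a lone array assumed to vary like the other groups, heat shock against sham gave 3096 and nsEP against heat shock 2526. Leaving out 1 array gave 4875 to 6545 and 3811 to 5692, and the replicate block 8082 and 7494. Lists called (6, 4 and 5) became 7 after heat shock and 8 between exposures with no filter, 0, 0 and 0 with an estimated correlation, 2 (nsEP) and 9 (heat shock) with fry, and 4 to 9, 4 to 7 and 4 to 6 leaving out 1 array. The block added the ATF4 and TGF-beta lists after heat shock (adjusted p = 0.0444 for both) and the matrix and mitotic lists between exposures (0.0491 and 0.0492); with the block and an estimated correlation their adjusted p was 0.650, 0.650, 0.733 and 0.711. The correlation between exposures ranged from 0.375 to 0.475. The median of all probe sets shifted by -0.14 (nsEP, median centring), -0.45 and -0.34 (heat shock, spike-in and ribosomal protein centring) and 0.46 and 0.35 (nsEP against heat shock). Signs turned for MT1X after heat shock with quantile normalization (-0.294). With ribosomal protein centring they turned for MT1X (-0.327), MT2A (-0.279) and RPS3 (-0.002) after heat shock and COX4I1 between exposures (0.007). With spike-in centring they turned after heat shock for CALD1 (-0.057), NDUFB5 (-0.091), RPL19 (-0.057), RPL30 (-0.084), RPL7 (-0.1), RPS3 (-0.11) and VIM (-0.087), and between exposures for CALD1 (0.002), COX4I1 (0.113), COX7C (0.018), RPL10A (0.093), RPL19 (0.023), RPL27 (0.034) and RPS14 (0.07). Beyond what fewer arrays or genes tested bring, the cause was not tested. Between nsEP and sham the block brought DNAJB1, DUSP1, MITF and the respiratory chain list below 0.05. With a filter that kept fewer, brighter probe sets, some dim genes and the interferon and histone lists had no value. Signal over background limits dim probe sets, whose detection calls were not used here.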

Other observations

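The lysosome, FOXO and zinc finger gene groups were chosen after single genes had been seen, and their tests were set before the values of the groups were computed. Their camera p-values are not adjusted and cannot be set beside the adjusted ones of the fixed lists. Unadjusted, camera with an estimated correlation gave p = 0.0227 for immediate early genes and p = 0.0420 for cholesterol synthesis after nsEP.

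Some genes of a lysosomal list rose after nsEP. A list of 35 genes with binding motifs for TFEB, the factor that governs lysosome formation, was drawn up without the genes that prompted it (NEU1, GLA and RRAGC). Of its 32 tested members 8 rose and 0 fell, 26 were higher, and the mean change was 0.35, above the median of 0.19 (camera p = 0.00115 with an estimated correlation). Most lysosomal enzymes in it were not called, such as CTSA (-0.08), CTSB (-0.08), CTSD (0.04), GUSB (-0.13), SGSH (-0.20) and GAA (0.04), nor was the membrane protein gene LAMP1 (0.08). The members that rose were the folliculin complex genes FLCN (1.02 ± 0.16), FNIP1 (1.08) and FNIP2 (1.37 ± 0.31), the proton pump genes ATP6V1C1 (0.98) and ATP6V1B2 (0.98), the cholesterol exporter gene NPC1 (1.12) and the autophagy genes MAP1LC3B (0.91) and SQSTM1 (0.66), all chosen after their values were seen. After heat shock 2 rose and 3 fell (camera p = 0.155 with an estimated correlation), and the direct comparison by camera gave p = 0.0667. A raised activity of TFEB or a related factor after nsEP may account for the rise of these members, as a hypothesis found and tested on the same arrays.

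Targets of FOXO factors, which promote growth arrest and catabolism when insulin signalling is low, were higher after both exposures. After nsEP 4 of 17 rose and 0 fell, 16 were higher, and the mean was 0.52 (camera p = 0.000898 with an estimated correlation). GABARAPL1 (1.14), BTG1 (0.95), BCL6 (0.86) and the insulin receptor substrate gene IRS2 (0.77 ± 0.16) rose, all chosen after their values were seen. After heat shock 11 rose, with a mean of 0.81 (camera p = 0.00247 with an estimated correlation), and IRS2 rose by 1.83 ± 0.16. The direct comparison of the list by camera gave p = 0.19 with an estimated correlation, and IRS2 was lower after nsEP than after heat shock (-1.06 ± 0.16). The sham arrays are shared by both comparisons, and no cause of the rise was tested.

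The third pattern weighed is a median difference of -0.133 after nsEP over 330 zinc finger (ZNF) genes, most of them not called. Of these genes 1 rose and 10 fell, and 214 were below 0 (p = 0.0245 with the preset and 0.24 with an estimated correlation). Drift of dim probe sets was set against random lists of equal signal. The 2.5th percentile of their medians was -0.07 and the matching upper percentile 0.02, around a median of -0.025. Genes of this signal as a whole were thus shifted by less than the ZNF genes. The random genes were drawn without regard to correlation between genes. With the estimated correlation the ZNF genes could not be told from other genes, so a drift that they share stays open. Under 4 other scalings the ZNF median was at most -0.125 and stayed below the median of all genes. That median was -0.036 as scaled, at most -0.028 under the 4, and -0.176 with median centring, where the ZNF median was -0.274. None of the 4 raised all genes by as much as the ZNF genes were lower, so these did not test scaling, which stays open. After heat shock the ZNF median was -0.462 against 0.02 to 0.15 for random lists (same percentiles). There 26 were higher and 125 lower (camera p = 0.0149 with an estimated correlation). In the direct comparison 96 were higher and 27 lower after nsEP than after heat shock. Its median was 0.278 against -0.16 to -0.04 for random lists (camera p = 0.0290 with an estimated correlation). The median was below 0 after both exposures, as a shared shift predicts, but further below after heat shock. The shared sham arrays and RNA quality stay open.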
